A study of Solanum tuberosum with 136 samples.

How the data were processed

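RNA was measured in 34 groups of 4 libraries of primary bud and flesh of potato tubers. Per the labels' protocols, total RNA was purified with the Qiagen RNeasy Plant Mini kit and sequenced as RNA-seq. The submitters' processing notes name Trimmomatic, HISAT2, SAMtools and StringTie, without versions or roles, and the genome build and annotation are not given in the sources used here. The authors deposited 2 tables, of counts per gene and of counts per transcript, and their values are whole numbers that sum to a different total in each library, so they were taken as counts without normalization. How reads shared by near-identical gene copies, overlapping genes or opposite strands were counted is not given in the sources used here, so values of such genes are uncertain.

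The gene table holds 32878 rows with a gene ID and 1 row that names no gene, which held between 1.76% and 2.95% of the counts of a library and was left out of library sizes and tests. No libraries had identical values, and 5374 genes had 0 counts in every library. The transcript table holds 44851 rows, of which 1 with 89 blank cells was left out. It lists 38 genes that the gene table does not list, and for 11 genes the sum over transcripts differs from the gene count. None of the gene IDs matched the table of gene names at hand (0 matches), which follows another assembly, so IDs are printed as deposited. For the same reason the gene lists planned before the data were examined (hormone, dormancy, cell cycle, cell wall, storage protein, starch, defence and other groups) were not tested.

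Groups were taken from the labels for tissue, treatment and time point. The numbers in the library titles were read as weeks, since they equal the sampling weeks of the series description. CPM, counts relative to the library total, were computed from the deposited counts with trimmed mean of M-values scaling. Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test) after its filter on low counts (minimum count 10, minimum total 15), with a threshold of 0.05 on Benjamini-Hochberg adjusted p-values. The 68 libraries of a tissue were fitted together, with 51 residual degrees of freedom, and the libraries of both tissues for comparisons between tissues. The 30 comparisons were the mean effect of ethylene over weeks 3 to 15, each week alone, the difference between weeks 15 and 3, each week after ethylene, the change from week 15 to week 18 (an interaction), control weeks 9 and 18 against week 0, any control week against week 0, bud against flesh at week 0 and the difference between tissues of the mean effect. Standard errors of log2 fold changes were derived from the F statistic. A fold change against a group without counts was replaced by a bound from a floor of 3 counts over the group, on the scale of the CPM printed.

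Genes named in the text were fixed before the data were examined as at most 2 IDs higher and 2 lower per comparison, largest first, among genes past the threshold with a mean of at least 5 CPM and, for the mean effect, the same sign in all 5 weeks. The storage position was chosen after the data were seen. It projects log2(CPM + 2) onto the difference between the control means of weeks 0 and 18 over genes 2-fold or more apart (2977 in bud, 1344 in flesh), and groups were compared with two-sided exact permutation tests. The overlaps, the genes past the threshold in all weeks, the set of 31 genes and the comparison of libraries were likewise chosen afterwards.

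The edgeR steps were tested on simulated counts with 200 genes changed 1.5-, 2- or 4-fold. Counts were drawn from the real library sizes and dispersions and from the mean of each gene over all libraries of the fit. No other gene differed between groups, and for the mean effect the fold was the same in all 5 weeks. The real data differ in both respects, so the shares may not carry over to them. For the bud mean effect (23891 genes), 53.8%, 81.5% and 83.1% were recovered at the 3 fold sizes, and 7 of 149 calls were genes that had not been changed. For bud week 15 (23879 genes) the shares were 23.1%, 53% and 81.8%, with 13 of 117 calls wrong, and for flesh week 15 (21095 genes) they were 43.1%, 62.1% and 82.8%, with 28 of 150 calls wrong, or 18.7%, which is above the nominal 5%. Of those 28 genes, 18 had a dispersion over 1. For bud week 18 after ethylene (23921 genes) 7 of 114 calls were wrong, for flesh week 18 (21083 genes) 10 of 112, for the flesh mean effect (21101 genes) 15 of 157, and for the tissues at week 0 (24266 genes) 12 of 99. DESeq2 on the counts simulated for bud week 15 gave 51 wrong calls of 154. Simulated storage positions were recovered with a largest error of 0.028 in bud and 0.042 in flesh. These libraries were made as mixtures of the control means of weeks 0 and 18. The errors therefore cover counting and replicate noise, and changes in other directions were not simulated.

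Library totals ranged from 16.6 M to 50.9 M counts. Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 test, a fit on the compared groups alone, the replicate number as a block, and leaving out each library in turn. Gene counts summed from the transcript table, a fit without 1 bud library and all alternatives for the storage position were added after the data were seen. Figures were drawn with matplotlib 3.10.9.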

Results

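RNA sequencing was used to measure gene expression in stored tubers of the potato cultivar Russet Burbank, kept with or without ethylene, a gaseous plant hormone that is used in potato stores to hold back sprouting. The question was how ethylene given during storage alters the transcripts of the bud, from which the sprout grows, and of the flesh, the storage tissue. Libraries came from the primary bud and from the flesh. Control tubers were sampled at weeks 0, 3, 6, 9, 12, 15, 16, 17 and 18 of storage. Tubers under 10 ppm ethylene were sampled at weeks 3, 6, 9, 12 and 15, and tubers returned to air after 15 weeks of ethylene were sampled at weeks 16, 17 and 18. This gave 34 groups of 4 libraries, 68 libraries per tissue. The total per library was between 16.6 M and 50.9 M counts, with a median of 31 M. The labels do not say that the 4 libraries of a group came from separate tubers, so the p-values measure the spread between these samples, which may be technical. Gene IDs are printed as the deposited table gives them, without product names, and levels are CPM (counts relative to the library total, scaled) as mean ± SD of 4 libraries.

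Storage without ethylene changed a large part of the transcripts in both tissues. In control buds, 6804 genes were higher and 5432 lower at week 18 than at week 0, of 24328 tested. Soltu.DM.09G030470 had no counts at week 0 and reached 45.5 ± 29.3 CPM (n = 4) at week 18, at least 2430-fold higher, and Soltu.DM.10G004810 went from no counts to 25.8 ± 4.02 CPM, at least 1370-fold higher. Soltu.DM.05G022670 was at 246 ± 16.2 CPM at week 0 and had no counts at week 18, at least 10900-fold lower. Soltu.DM.05G022690 was at 396 ± 17.8 CPM at week 0 and at 0.113 ± 0.225 CPM at week 18, where replicate 3 held all of its counts, and fell by 11.65 on the log2 scale (SE 0.41). The adjusted p-values of these genes from edgeR's quasi-likelihood test were 8.11e-14, 8.57e-13, 8.99e-25 and 1.42e-33. At week 9 the control buds already differed from week 0 in 13602 genes, and 20369 genes differed between week 0 and any of the later weeks. Bounds of the form "at least" are set by a floor of 3 counts over the group without counts and cover counting error only.

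Control flesh changed in fewer genes, with 3686 higher and 4064 lower at week 18 than at week 0, of 21718 tested. Soltu.DM.12G004090 rose from no counts to 20.1 ± 5.14 CPM (n = 4), at least 704-fold, and Soltu.DM.02G020800 from no counts to 4.59 ± 1.48 CPM, at least 160-fold. Soltu.DM.05G022700 fell from 72.6 ± 14 CPM to no counts, at least 2550-fold, and Soltu.DM.03G023590 fell from 66.8 ± 9.18 CPM to no counts, at least 2340-fold. The adjusted p-values (edgeR) were 1.1e-22, 2.64e-10, 3.87e-34 and 6.19e-06. Counts of Soltu.DM.03G023590 were uneven within groups between those weeks, so its values are uncertain. In control flesh it was at 0 in 1 library of week 6, where another held 130 CPM. It was at 0 in 2 libraries of week 9 and in 2 of week 12. The flesh of week 9 differed from that of week 0 in 6551 genes, and 14499 genes differed between week 0 and any later week. The storage changes of the tissues overlapped: 2034 genes rose in both, where independent lists would share 965.5, and 2384 fell in both, where independent lists would share 980.2, among 21373 genes tested in both. Opposite directions were taken by 605 genes, against 1953.8 for independent lists.

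Bud and flesh differed at week 0 in 12233 of 24835 genes, 7008 higher in bud and 5225 higher in flesh. Soltu.DM.05G023610 had no counts in flesh and was at least 3440-fold higher in bud. Soltu.DM.09G025040 was at 90 ± 19.9 CPM (n = 4) in bud and had no counts in flesh, at least 3000-fold higher. Soltu.DM.05G007940 had no counts in bud and 1.05 ± 0.753 CPM in flesh, at least 59.4-fold lower in bud, and Soltu.DM.07G027160 was at 0.595 ± 0.17 CPM in bud and 20 ± 5.59 CPM in flesh. The adjusted p-values (edgeR) were 1.56e-28, 2.16e-30, 6.32e-05 and 1.03e-30.

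Ethylene altered more genes in the bud than passed the same test in the flesh. Averaged over weeks 3 to 15, 3216 genes were higher and 3681 lower in buds under ethylene than in control buds, of 24328 tested, and 804 of them differed 2-fold or more. Soltu.DM.09G028720 was at 15.7 ± 6.65 CPM (n = 4) under ethylene and 4.28 ± 0.997 CPM in the control at week 12. Its control groups of weeks 9 and 15 had no counts, so no mean fold is given (adjusted p = 0.000147, edgeR). Soltu.DM.01G041870 was 13.2-fold higher over the 5 weeks (log2 difference 3.73 ± 0.28, SE, adjusted p = 5.68e-18), with 31.3 ± 9.66 CPM against 1.44 ± 0.538 CPM at week 9. Soltu.DM.04G035630 was at 5.18 ± 3.11 CPM under ethylene and 35.5 ± 10.4 CPM in the control at week 15, and Soltu.DM.12G029260 at 6.39 ± 1.03 against 13.6 ± 0.62 CPM. Their adjusted p-values for the mean of the weeks were 0.0165 and 1.59e-06. The ethylene groups were without counts of Soltu.DM.04G035630 at week 3 and of Soltu.DM.12G029260 at week 9. The call of Soltu.DM.04G035630 ended without control replicate 1 of week 3 (adjusted p = 1).

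A set of genes was past the threshold in the same direction at every one of the 5 ethylene weeks: 26 higher and 11 lower in buds, and 3 higher and 2 lower in flesh, while lists independent between weeks would give 0.0191, 0.0216, 0.000343 and 0.000471 genes. The weeks share an estimate of the spread for each gene, so they are not fully independent. Some of the 26 have neighbouring IDs and close values, such as Soltu.DM.01G041860 and Soltu.DM.01G041870 (mean log2 differences 3.66 and 3.73), and may not be separate responses. Soltu.DM.07G025000, singled out after its values were seen, was the only gene in the lists of both tissues. It was at 15.8 ± 3.86 CPM (n = 4) under ethylene against 4.34 ± 1.17 CPM in control buds at week 12, and at 16.3 ± 3.81 against 4.34 ± 1.33 CPM in flesh. Its mean log2 difference was 1.66 ± 0.11 (SE) in bud and 2.29 ± 0.15 in flesh (adjusted p = 1.44e-18 and 2.7e-20, edgeR). The other flesh genes that were higher in all weeks were Soltu.DM.04G033210, with a mean log2 difference of 0.84 ± 0.05, and Soltu.DM.03G019560, with 0.33 ± 0.02. Without replicate 1 of the buds of week 17 after ethylene, described below in the account of week 17, the bud lists held 67 higher and 21 lower genes, including 26 and 10 of those above.

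**Figure D1:**
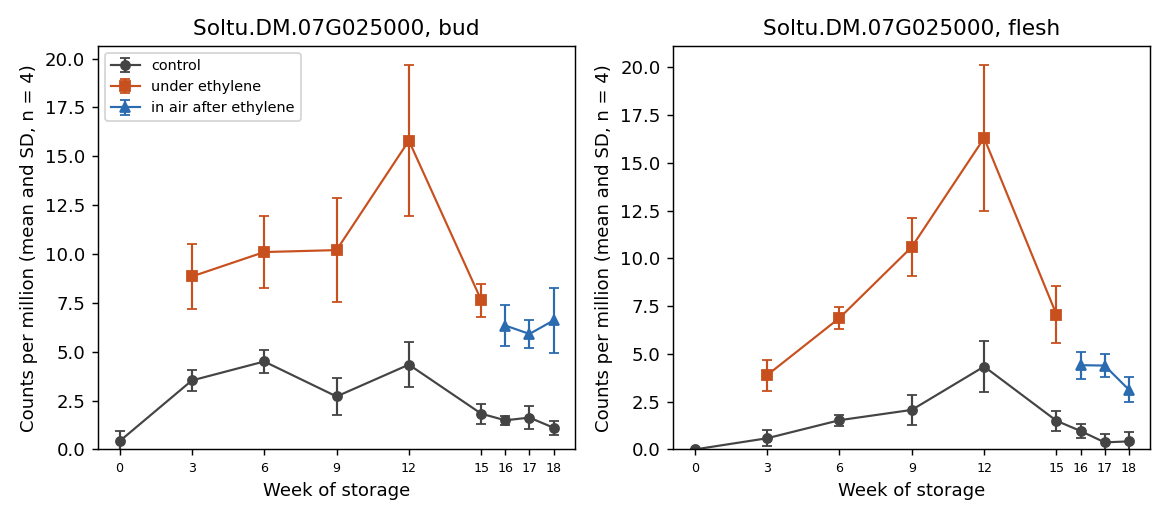
CPM of Soltu.DM.07G025000 (y axis, linear) by week of storage (x axis) in bud (left) and flesh (right), as means with SD bars of 4 libraries for control tubers (circles), tubers under ethylene (squares) and tubers in air after ethylene (triangles). Levels under ethylene lay above the control at each of the 5 weeks and were still above it at week 18, at 6.6 ± 1.65 against 1.11 ± 0.363 CPM in bud and 3.13 ± 0.647 against 0.421 ± 0.507 CPM in flesh.

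Taken week by week, the bud response was largest at week 15, when 3336 genes were higher and 4167 lower under ethylene. The counts of genes past the threshold were 1256 at week 3, 3718 at week 6, 2317 at week 9, 2832 at week 12 and 7503 at week 15. The ethylene effect differed between weeks 15 and 3 in 3376 genes, tested as an interaction. Fitted with only the groups compared, week 3 gave 3803 genes, against 3623 at week 6 in the same kind of fit, and the interaction gave 5245. At week 3, leaving out ethylene replicate 1, control replicate 4 or ethylene replicate 2 gave 535, 597 and 811 genes; at week 9, leaving out control replicate 1 or ethylene replicate 4 gave 1444 and 1459; at week 12, leaving out ethylene replicate 4 gave 1858. A fit without replicate 1 of the buds of week 17 after ethylene gave 2358 genes at week 3, 5446 at week 6, 3511 at week 9, 3892 at week 12 and 9165 at week 15.

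**Figure D2:**
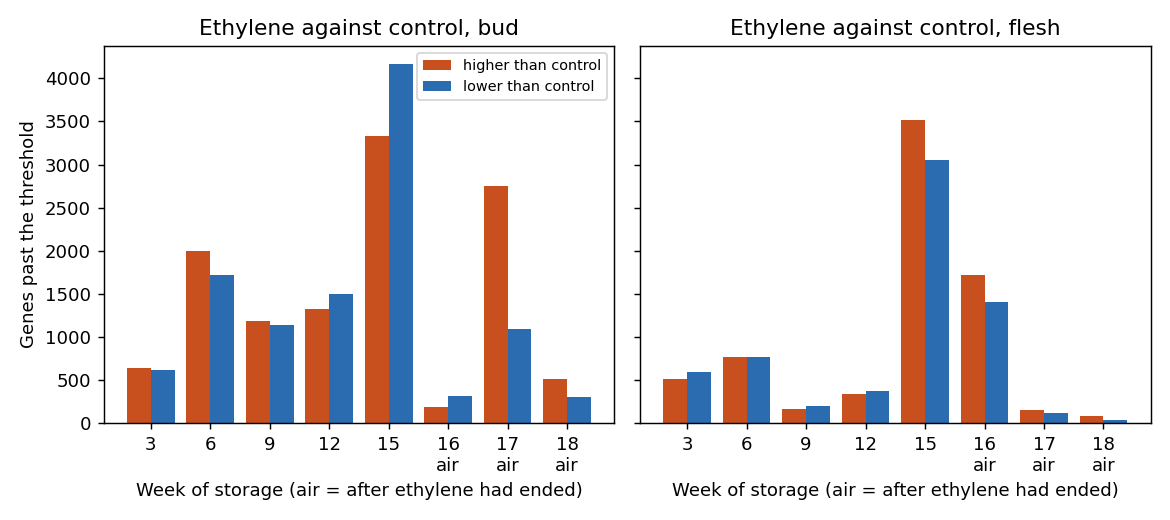
Number of genes past the threshold (y axis, starting at 0) higher or lower than in the control of the same week (x axis) in bud (left) and flesh (right), under ethylene up to week 15 and in air after ethylene at weeks 16, 17 and 18. The tallest bars stand at week 15, with 4167 lower genes in bud and 3515 higher genes in flesh.

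The bud response was set against the changes that storage itself made in control tubers. Of 3859 genes that rose at least 2-fold in control buds from week 0 to week 18, 46.5% were lower under ethylene at week 15 and 3.3% higher, while at week 9 4.5% were lower and 3.6% higher, and at week 3 1.1% were lower and 3.9% higher. Of 2108 genes that fell at least 2-fold, 43.8% were higher under ethylene at week 15 and 3.3% lower, and at week 3 1.9% were higher and 9.7% lower. At weeks 6, 9 and 12, 35.9%, 24.3% and 35.7% of them were higher and 1.9%, 2.2% and 1.4% lower. Of all bud genes called at week 15, 31.6% had no call for storage. In flesh, 31.5% of 1385 genes that fell during storage were higher under ethylene at week 15, while of 1268 genes that rose 18.5% were higher and 16.2% lower. A storage position was computed for each library over genes with control means at least 2-fold apart, with 0 at control week 0 and 1 at control week 18. Control buds stood at 0.56 ± 0.04 (SD, n = 4) at week 9, 0.68 ± 0.06 at week 12 and 0.96 ± 0.01 at week 15. Buds under ethylene stood at 0.42 ± 0.07, 0.4 ± 0.03 and 0.52 ± 0.03. At weeks 6, 9, 12 and 15 all 4 ethylene buds lay below every control, by -0.18, -0.15, -0.28 and -0.44, and at week 3 all 4 lay above every control, by 0.09. Each of these had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.0334 after adjustment over 14 tests.

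Flesh showed smaller shifts of the same measure. It stood above the controls by 0.08 at week 3 and below them by -0.07, -0.08 and -0.13 at weeks 9, 12 and 15 (exact permutation p = 0.0286 each, adjusted 0.0334), and differed by 0.05 at week 6 (exact p = 0.0857, adjusted 0.0923). The call at week 9 ended without control replicate 1 or 3 of week 18 (exact p = 0.0571 each, differences -0.07 and -0.06). With positions drawn instead from control week 9 to week 18, a choice made after the data were seen, the bud differences of weeks 6, 9 and 15 kept their direction and their exact p of 0.0286, while the bud difference of week 3 became -0.03 (exact p = 0.143) and that of week 12 was -0.09 (exact p = 0.114). In flesh, no difference of weeks 3 to 15 passed the exact test on that scale, and week 6 changed sign to -0.01. The flesh differences of weeks 9, 12 and 15 kept their direction there. The controls of week 9 set the 0 of that scale and entered the choice of its genes. The week 9 comparisons on it, in bud and flesh, are therefore no independent check.

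**Figure D3:**
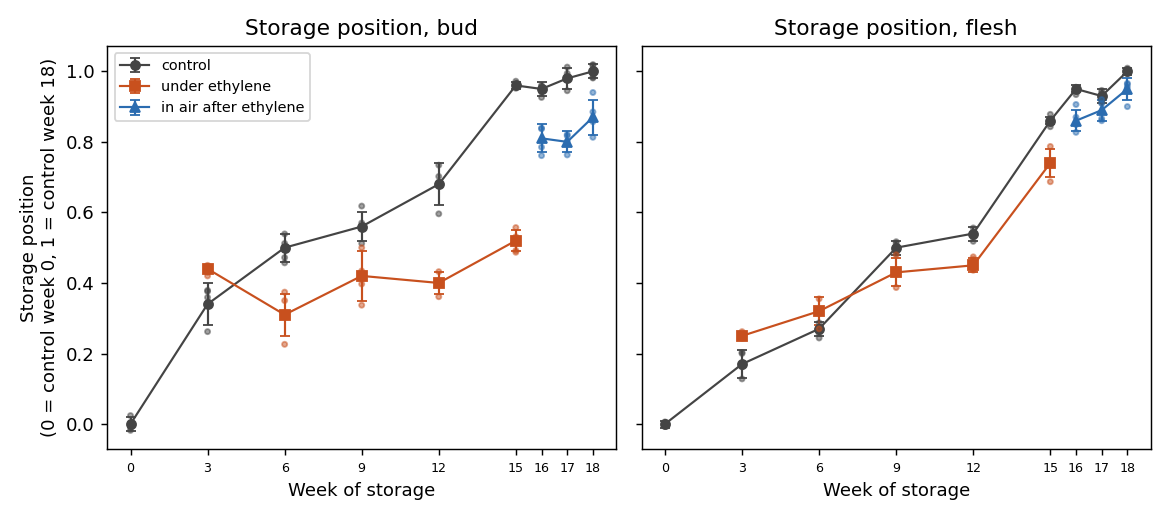
Storage position (y axis, 0 at control week 0 and 1 at control week 18) by week of storage (x axis) in bud (left) and flesh (right). Small points are libraries, and larger symbols with bars are means and SD of 4 libraries for control tubers, tubers under ethylene and tubers in air after ethylene. At week 15 the buds under ethylene lay at 0.52 ± 0.03 and the control buds at 0.96 ± 0.01.

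In flesh, the mean over weeks 3 to 15 was higher under ethylene for 1511 genes and lower for 1272, of 21718 tested. Of the genes called, 239 differed 2-fold or more. This mean covers weeks that partly opposed each other. Between weeks 6 and 15, 838 genes were past the threshold in opposite directions, against 232.7 for independent lists. Fewer genes than independent lists would share were higher at both of these weeks, or lower at both. Between week 15 and weeks 3, 9 and 12, opposite calls were fewer than for independent lists. Soltu.DM.10G024810 was at 11.9 ± 1.66 CPM (n = 4) under ethylene against 3.92 ± 0.632 CPM at week 9, and at 1.66 ± 0.224 CPM against no counts at week 15 (adjusted p = 1.12e-11, edgeR). Soltu.DM.08G003110 was 3.09-fold higher over the weeks (log2 difference 1.63 ± 0.12, SE, adjusted p = 1.17e-17), with 26.7 ± 7.79 against 7.7 ± 2.47 CPM at week 12. Soltu.DM.07G017540 was 3.02-fold lower (log2 difference -1.59 ± 0.39, adjusted p = 0.00195), with 1.22 ± 0.859 against 5.53 ± 1.26 CPM at week 15. At weeks 3, 6, 9 and 12 its means were 0.414 CPM or less under ethylene and 1.5 CPM or less in the controls. Its mean fold thus rests partly on levels near 0. Soltu.DM.06G005570 was past the threshold as lower (adjusted p = 0.023), but it stood at 0 in 80 of the libraries of both tissues and between 407 and 733 CPM in the other 56, within groups, and without control replicate 1 of week 3 its adjusted p was 1.

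The flesh counts by week were 1106 genes at week 3, 1538 at week 6, 364 at week 9, 712 at week 12 and 6571 at week 15, of which 3515 were higher and 3056 lower at week 15. The effect differed between weeks 15 and 3 in 3268 genes, tested as an interaction. Fitted with only the groups compared, the counts were 1172 at week 3, 3901 at week 6, 679 at week 9, 297 at week 12 and 4312 at week 15, so the order of the weeks depends on the fit. The direction of the smaller counts depended on the scaling: 164 higher and 200 lower at week 9 became 173 and 140 with the DESeq2 size factors, and 339 and 373 at week 12 became 358 and 261. Leaving out 1 library lowered the count to 726 at week 3 (ethylene replicate 1), to 952, 987 and 948 at week 6 (control 1, ethylene 1, ethylene 2), to 200, 227, 190 and 215 at week 9 (control 1, 2 and 4, ethylene 1) and to 413, 427 and 429 at week 12 (control 2 and 3, ethylene 4).

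The lists of genes that responded to ethylene overlapped between the tissues. Of the genes tested in both, 973 were higher in both over weeks 3 to 15, against 213.9 for independent lists, 693 were lower in both, against 207.7, and 49 went in opposite directions, against 426.6. No library entered both lists, but bud and flesh libraries of the same number had a mean correlation of 0.11 after removal of group means (34 of 68 over 0.1, other numbers -0.035), and whether they share a tuber is not given in the sources used here. A test of the difference between the tissues' mean effects called 1381 of 24835 genes, 944 with a more positive effect in bud and 437 with a more positive effect in flesh. These were 784 and 489 with the DESeq2 size factors and 997 and 820 with the DESeq2 test. Soltu.DM.05G022690, whose level fell with storage in both tissues, was called with a more positive effect in bud (adjusted p = 0.00524, edgeR; no fold is given because a bud control group had no counts), with 23.3 ± 13.8 against 3.99 ± 1.42 CPM (n = 4) in bud and 11.9 ± 3.99 against 9.91 ± 0.243 CPM in flesh at week 12. Soltu.DM.06G005570 was called with the larger log2 difference, and rests on the all-or-none counts described above. Soltu.DM.06G025730 and Soltu.DM.01G027950 were called as more positive in flesh (adjusted p = 0.0104 and 0.00737), where 4 and 2 of their control groups had no counts, so no fold is given. All 4 of these calls ended when 1 library was left out: adjusted p = 1 for Soltu.DM.06G005570 without bud ethylene week 12 replicate 3 or flesh control week 3 replicate 1, 0.0569 for Soltu.DM.05G022690 without flesh control week 15 replicate 1, 1 for Soltu.DM.06G025730 without flesh ethylene week 15 replicate 1, and 1 for Soltu.DM.01G027950 without flesh ethylene week 12 replicate 2.

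After the return to air the buds still differed from the controls, and part of the genes that were higher at every ethylene week were higher then too. Of the 26 bud genes that were higher in all 5 ethylene weeks, 9, 15 and 17 were past the threshold as higher at weeks 16, 17 and 18, where independent lists would share 0.2, 2.9 and 0.5. Their median log2 differences were 0.5, 0.55 and 0.84, and 21, 23 and 25 of them had a positive difference. The value of week 17 includes replicate 1, which stood apart from its group, and in the fit without it 21, 26 and 45 of 67 such genes were past the threshold as higher at the 3 weeks. Of the 11 bud genes that were lower in all 5 weeks, 3, 3 and 4 were past the threshold as lower (median log2 differences -0.16, -0.08 and -0.27). The 3 flesh genes higher in all weeks were past the threshold at each of the 3 weeks, and of the 2 lower flesh genes 1, 2 and 0 were. Soltu.DM.01G041870 had log2 differences of 4.77, 5.98 and 6.25 at weeks 16, 17 and 18 in bud (adjusted p = 0.014, 7.8e-05 and 2.6e-05, edgeR). The storage position of the buds was 0.81 ± 0.04 (SD, n = 4) at week 16 and 0.8 ± 0.03 at week 17, against 0.95 ± 0.02 and 0.98 ± 0.03 in the controls, each with an exact permutation p of 0.0286 (adjusted 0.0334). With positions drawn from control week 9 the difference of week 16 was -0.08 (exact p = 0.171).

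At week 18, 3 weeks after ethylene ended, 513 genes were higher and 305 lower in buds than in the controls. Soltu.DM.09G007020 had no counts in control buds and 29.1 ± 20.7 CPM (n = 4) after ethylene, at least 1290-fold higher, and Soltu.DM.01G005180 had none and 8.43 ± 6.2 CPM, at least 376-fold higher. Soltu.DM.02G024670 was lower, at 200 ± 91.7 against 933 ± 99.8 CPM, and Soltu.DM.05G023610 was lower, at 55.8 ± 6.63 against 237 ± 50.6 CPM. Their adjusted p-values (edgeR) were 3.02e-05, 0.00711, 3.25e-05 and 6.96e-08. The call of Soltu.DM.01G005180 ended without replicate 1 after ethylene (adjusted p = 0.0595). The count of 818 genes became 378, 538 and 459 without replicate 1 after ethylene, control replicate 1 and control replicate 2, 1685 in the fit without replicate 1 of week 17 after ethylene and 1490 with only the groups compared.

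At week 16 after ethylene 187 genes were higher and 312 lower in buds, and at week 17 there were 2748 higher and 1098 lower. The week 17 count rested on replicate 1, which stood apart from its group: the SD of its log2 differences from the other 3 libraries was 1.07, the next highest SD in the series was 0.5 and the median 0.24. Without it 776 genes were higher and 233 lower at week 17, and without replicate 3 of that group the count was 6226. A fit on the 8 libraries of week 17 alone called 0 genes with edgeR, with 2345 at an unadjusted p under 0.05, while DESeq2 on all bud libraries called 4133. The week 16 count of 499 became 898 in the fit without replicate 1 of week 17, 1293 with only the groups compared, and 296, 260, 268 and 311 without replicates 3 and 4 after ethylene and control replicates 1 and 2 of week 16.

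A set of 31 genes was picked because they reached 10 CPM in that replicate and averaged under 0.1 CPM outside the groups after ethylene. Summed over the set, the 4 buds of week 17 after ethylene held 15.6 to 1000 CPM (here of the unscaled totals), and the controls 2.58 to 4.29. At week 18 the buds after ethylene held 18.3 or more and the controls 4.64 to 6.37, and at week 16 they held 0.223 to 3.6 against 1.48 to 4.79. The controls are low by the choice of the genes, so no test is given for the set. With 40 genes chosen in the same way but without the bud controls of weeks 16, 17 and 18, of which 30 are in the first set, the buds of week 18 after ethylene held 96 to 170 CPM and the controls 66.8 or more, with 1 of the 4 above every control (exact permutation p = 0.257, adjusted 0.257 over 2 weeks). At week 16 they held 2.07 to 9.94 against 12.8 to 26.1 (exact p = 0.0286, adjusted 0.0572).

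**Figure D4:**
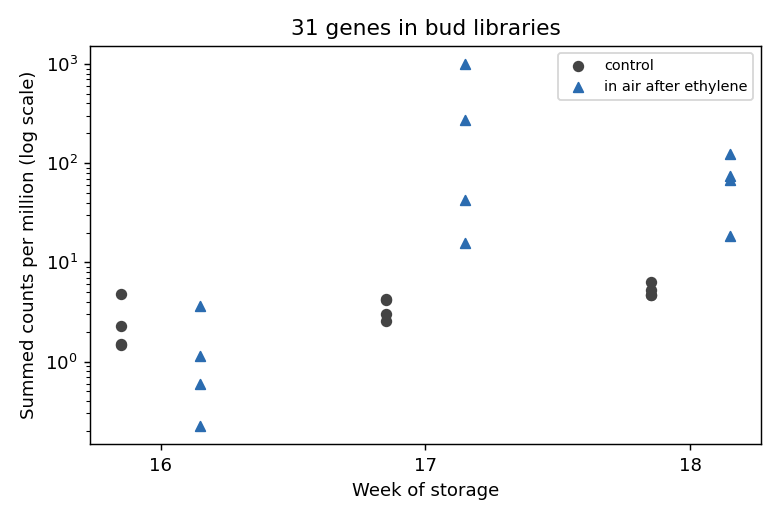
Summed CPM (y axis, log scale) of 31 genes in each bud library of weeks 16, 17 and 18 (x axis), for controls (circles) and buds in air after ethylene (triangles). At weeks 17 and 18 the 4 libraries after ethylene lay above the controls, from 15.6 and 18.3 upward. The genes were chosen for low levels outside the groups after ethylene, so that low levels in these controls are part of the choice.

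The flesh differed from its controls in 1722 higher and 1402 lower genes at week 16, in 279 genes at week 17, and in 87 higher and 35 lower genes at week 18. Between week 15 under ethylene and week 16 after it, 1596 flesh genes were past the threshold in opposite directions, against 469.2 for independent lists, while 198 were higher at both weeks and 94 lower at both. The 100 genes called at least 4-fold higher in flesh than in bud at week 0, with at least 5 CPM in flesh, moved with it. They went from 35 higher and 6 lower at week 15 to 4 higher and 31 lower at week 16. Their mean log2 level in the controls went from 4.35 ± 0.08 (SD, n = 4) to 4.54 ± 0.07. In the treated flesh it went from 4.58 ± 0.04 under ethylene to 4.26 ± 0.1 after it. The nearest controls were crossed: flesh of week 15 under ethylene lay nearest to control week 16 (distance 0.33, against 0.41 from week 15), and flesh of week 16 after ethylene nearest to control week 15 (0.23, against 0.29 from week 16). These values were read after the data were seen, and whether the controls or the treated samples of these weeks account for the reversal was not tested. At week 18, Soltu.DM.02G022920 and Soltu.DM.08G027280 were called as higher, but 139 and 85.5 CPM came from replicate 1 alone, and without it their adjusted p-values (edgeR) were 0.838 and 0.866. Soltu.DM.07G024510 was lower, at 7.17 ± 2.89 (n = 4) against 16.9 ± 3.55 CPM (adjusted p = 0.00112, and 0.0579 with only the groups compared), and Soltu.DM.02G020770 was lower, at 6.46 ± 0.814 against 11.6 ± 1.83 CPM (adjusted p = 0.0209, 0.195 with only the groups compared, and 0.149, 0.0559, 0.0804 and 0.0602 without replicate 1 after ethylene and control replicates 2, 3 and 4). The call of Soltu.DM.08G027280 also ended without any 1 of the 4 controls (adjusted p = 0.0743, 0.0739, 0.057 and 0.0651). The flesh storage position was 0.86 ± 0.03 against 0.95 ± 0.01 at week 16 (exact p = 0.0286, adjusted 0.0334) and 0.89 ± 0.03 against 0.93 ± 0.02 at week 17 (exact p = 0.114). With only the groups compared the counts of weeks 17 and 18 were 93 and 11, and with DESeq2 430 and 479. The week 18 count was 21, 185, 212, 54 and 73 without replicates 1, 3 and 4 after ethylene and control replicates 1 and 2; the week 17 count was 76, 152 and 151 without replicate 1 after ethylene and control replicates 2 and 4; the week 16 count was 2051 and 2073 without replicate 4 after ethylene and control replicate 1.

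The change in the ethylene effect from the last week of treatment to week 18 was tested as an interaction. In bud it passed for 3634 genes, 2362 with a more positive difference from the control at week 18 and 1272 with a more negative one. Soltu.DM.04G026490 went from 1.57 ± 1.98 against 5.95 ± 2.14 CPM (n = 4) at week 15 to 200 against 13.3 ± 5.56 CPM at week 18, a change of 5.79 ± 1.04 (log2, SE), and Soltu.DM.01G027180 from 2.29 ± 1.79 against 28 ± 7.74 CPM to 13 ± 3.03 against 9.91 ± 2.76 CPM. Soltu.DM.03G015500 went from 24.9 ± 10.6 against 1.44 ± 0.776 CPM to 5.86 ± 0.738 against 3.05 ± 1.04 CPM, and Soltu.DM.05G018970 from 13.5 ± 8.45 against 1.21 ± 0.228 CPM to 9.28 ± 2.77 against 5.53 ± 0.3 CPM. The adjusted p-values (edgeR) were 4.34e-05, 1e-07, 0.00161 and 0.000827, and DESeq2 did not call Soltu.DM.01G027180 (adjusted p = 0.153).

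In flesh the same interaction passed for 2236 genes, 1095 more positive and 1141 more negative at week 18. Soltu.DM.01G021510 went from 3.41 ± 0.776 against 8.82 ± 2.06 CPM (n = 4) to 4.28 ± 0.795 against 1.94 ± 2.35 CPM, and Soltu.DM.07G017540 from 1.22 ± 0.859 against 5.53 ± 1.26 CPM to 13.2 ± 2.52 against 17 ± 2.68 CPM. Soltu.DM.01G026780 went from 2.61 ± 1.6 against 0.194 ± 0.388 CPM to 0.591 ± 0.683 against 1.76 ± 0.833 CPM, and Soltu.DM.06G028510 from 4.8 ± 3.19 against 0.742 ± 0.433 CPM to no counts against 0.32 ± 0.447 CPM. The adjusted p-values (edgeR) were 0.00153, 0.00345, 0.000218 and 0.0316. DESeq2 did not call Soltu.DM.07G017540 (adjusted p = 0.459), and the call of Soltu.DM.06G028510 ended without replicate 2 or 4 of either group of week 18 (adjusted p = 0.0502 and 0.0674 after ethylene, 0.0651 and 0.278 in the controls) and with only the groups compared (adjusted p = 0.118). The count was 864 with only the groups compared and 1222 without replicate 4 after ethylene of week 18.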

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

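Single samples were compared with the other 3 of their group by Dixon's test in 91 groups, of which 8 held a far value; chance gives about 1 in 20 groups. In 4 of the 8 the other 3 samples had no counts, which fixes the outcome of the test for any count in the fourth, so the 8 cannot be set against that share. The storage positions, 34 of those groups, and the test of genes listed only by transcript were chosen after the data were seen. The storage position of control bud replicate 4 of week 3 was 0.26, far from the others of its group. The position of flesh replicate 1 of week 18 after ethylene was 0.9, also far from the others. In the same flesh replicate 1 of week 18 after ethylene, Soltu.DM.02G022920 was at 139 CPM and Soltu.DM.08G027280 at 85.5 CPM, each far from the other 3. In control flesh replicate 3 of week 18 both genes were at 0.622 CPM and the other 3 controls had no counts. Soltu.DM.01G026780 was at 0.777 CPM in control flesh replicate 2 of week 15 and had no counts in the other 3. Soltu.DM.05G022690 was at 0.451 CPM in control bud replicate 3 of week 18 and had no counts in the other 3.

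Differences between groups were tested as interactions with edgeR. The mean effect of ethylene differed between bud and flesh in 1381 genes. The effect differed between weeks 15 and 3 in 3376 genes in bud and 3268 in flesh. The difference from the control changed between week 15 under ethylene and week 18 after it in 3634 genes in bud and 2236 in flesh.

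Genes outside the gene table were tested too. Of the 38 genes listed only by transcript, 11 of 33 tested were past the threshold for the mean effect of ethylene in bud, and 13 of 32 tested in flesh. Among all genes tested from the gene table, 28.4% passed in bud and 12.8% in flesh, so the bud count lies near the general share.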

How the results depend on the processing

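All 30 counts of genes stayed within 1.5 times, and all 40 values of named genes kept their direction and side of the threshold, with DESeq2 size factors, without the filter on low counts, with the replicate number as a block and with counts summed from transcripts. Within a tissue replicate numbers paired samples little over all genes: libraries of the same number in the control and treated groups of a week had, after removal of group means, a mean correlation of 0.036 in bud (lowest -0.268, 10 of 32 over 0.1) and 0.014 in flesh (lowest -0.127, 1 of 32 over 0.1). In the storage position of buds, however, replicate 4 was lowest in every group except week 0 and weeks 17 and 18 after ethylene. A shared block is thus not ruled out there, and the exact tests of positions took no account of it. The replicate block moved counts by at most 1.33 times (7019 genes for the mean effect in bud and 2910 in flesh). The gene lists planned were not run, and 3 named genes had no value when only their groups were fitted. No named gene reversed. The cause of the changes below was not tested, except that fits on fewer libraries had fewer residual degrees of freedom.

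Fitted with only the groups compared, bud counts were 3803 at week 3, 5245 for week 15 minus week 3, and 1293, 0 and 1490 at weeks 16, 17 and 18 after ethylene; flesh counts were 3901, 679, 297 and 4312 at weeks 6, 9, 12 and 15, 93 and 11 at weeks 17 and 18 after ethylene, and 864 for the change to week 18. In that fit Soltu.DM.07G024510 was at -1.25 (adjusted p = 0.0579, edgeR), Soltu.DM.02G020770 at -0.85 (adjusted p = 0.195) and the call of Soltu.DM.06G028510 ended (adjusted p = 0.118). With DESeq2, flesh counts were 430 and 479 at weeks 17 and 18 after ethylene, Soltu.DM.01G027180 was at 4 (adjusted p = 0.153) and Soltu.DM.07G017540 at 1.84 (adjusted p = 0.459) for the change to week 18. In the fit without replicate 1 of bud week 17 after ethylene, bud counts were 2358 and 3511 at weeks 3 and 9, and 898, 1009 and 1685 at weeks 16, 17 and 18.

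On the storage scale from control week 9 to week 18, bud differences were -0.03 at week 3 (reversed, exact p = 0.143), -0.09 at week 12 (exact p = 0.114) and -0.08 at week 16 (exact p = 0.171). Flesh differences were 0.01, -0.01 (reversed), -0.08, -0.06 and -0.11 at weeks 3, 6, 9, 12 and 15 (exact p = 0.6, 0.714, 0.0571, 0.0857 and 0.0571), and -0.11 at week 17, now past the threshold (exact p = 0.0286). The week 9 comparison uses the controls that set the 0 of this scale.

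Leaving out 1 library at a time moved 37 of 464 counts, weakened 22 of 928 named-gene values and 2 of 224 positions. The ranges for bud were 535 to 1107 at week 3, 1444 to 2180 at week 9, 1858 to 2597 at week 12, and 260 to 469, 1009 to 6226 and 378 to 881 at weeks 16, 17 and 18 after ethylene. For flesh they were 726 to 1089, 948 to 1426, 190 to 332 and 413 to 586 at weeks 3, 6, 9 and 12, 2051 to 3326, 76 to 288 and 21 to 212 at weeks 16, 17 and 18 after ethylene, and 1222 to 2666 for the change to week 18. The flesh position of week 9 ranged from -0.08 to -0.05.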

Other observations

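Genes called at least 4-fold apart between bud and flesh at week 0, with at least 5 CPM in the higher tissue, were followed under ethylene. The sets were chosen after the data were seen, and no test compares them with other genes or the weeks with each other. Of 1021 genes higher in bud, 24 were higher and 165 lower in buds at week 3, 433 and 56 at week 6, 395 and 26 at week 9, 424 and 62 at week 12, and 427 and 155 at week 15. In flesh, where 928 of them were tested, 27 were higher and 28 lower at week 3, 27 higher and 24 lower at week 6, 32 were higher and 1 lower at week 9, and 237 were higher and 31 lower at week 15. Of 100 genes higher in flesh, 15 were higher and 1 lower in buds at week 3, 20 and 2 at week 6, and 26 and 7 at week 15. At weeks 9 and 12 they were 5 and 12, and 1 and 12. In flesh 35 were higher and 6 lower at week 15 and 4 and 31 at week 16. The bud genes of week 9 under ethylene and of week 18 after ethylene overlapped, with 260 higher at both, against 24.9 for independent lists, and 172 lower at both, against 14.2. This was not particular to week 9. For weeks 12 and 18, 274 were higher at both, against 28, and 167 lower at both, against 18.8.

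The tests of the 3 patterns that follow were chosen after the results were seen. Bud replicate 1 of week 17 after ethylene stood apart from its group, with 1184 genes off by 4-fold or more. A low count total is excluded, since 36 libraries had fewer counts. Even so, 19802 genes had counts in it, against 22560, 23032 and 23000 in replicates 2, 3 and 4 of its group. Whether RNA or library quality accounts for this was not tested. An exchange with a library of another group of the series is excluded, since the SD of the replicate from the nearest group was 0.97. An exchange with a sample from outside stays open. Flesh in the sample is excluded as the source of the 31 genes. No flesh library after ethylene, the ones that did not enter the choice of these genes, held them at more than 27 CPM in sum, against 1000 in the replicate. Flesh is also excluded as the cause of the genes the library lacks. Genes higher in flesh had a median log2 difference of 0.21 (upper quartile 0.97) where 1.7 was needed. A smaller share of flesh stays open. Carry-over of that library is excluded as the whole source of the 31 genes in replicate 4, which would take a share of 27.4%. Genes the library lacks had a median log2 difference of -0.1 there (quartiles -0.21 and 0.03) where -0.46 was needed. Replicate 4 entered the choice of these genes, and a smaller share of carry-over stays open. For the other buds carry-over cannot be told. The chi-square per degree of freedom of the proportions, 11.2 or more, covers counting error only and lies within the values between replicates. A biological difference was not tested.

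A hypothesis is that ethylene delayed the storage course of the buds. If so, buds of week 15 under ethylene would lie nearest to controls of an earlier week, and they lay nearest to control week 12, at a distance of 0.35 against 0.57 from control week 15; buds of weeks 6 and 12 under ethylene lay nearest to controls of their own week (0.39 and 0.36), and those of week 9 as near to week 6 as to week 9 (0.37). In flesh of week 15 the nearest control was that of week 16 while the storage position lay behind the control, so a delay there cannot be told. Flesh tissue in the bud samples is excluded as the whole cause, since a mixture with control buds would need 99% flesh and a mean log2 level of flesh genes of 4.62, where the buds had 2.96 ± 0.06 (SD) and control buds 2.74; a smaller share stays open, since 26 of 100 flesh genes were higher and 7 lower. On the storage position, buds under ethylene stood at 0.44 ± 0.01 (SD) at week 3, ahead of the control at 0.34 ± 0.06. At week 6 they stood at 0.31 ± 0.06. A course that is only delayed would neither lead the control nor move back, so on this scale these values argue against a delay alone. On the scale from control week 9 the lead of week 3 was absent and the bud difference of week 12 was -0.09. Whether a delay acts beside a separate response that opposes the storage changes could not be told.

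Soltu.DM.06G005570 stood at 0 in 80 libraries and averaged 604 CPM in 56, and 28 groups held both kinds. That its reads went to the row without a gene name is excluded, since that row changed by -103 ± 80.8 CPM (SE) where the gene was at 0. Whether they went to 1 other gene cannot be told, since the largest gain of any gene was 282 ± 173 CPM. No biological explanation was tested.

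Whether a count could come from any grouping of the same libraries was tested by splits, with a fit on those libraries only; the test was fixed before its values were seen, except for bud week 17 after ethylene, where it was chosen afterwards. With 35 splits, the real split gave in bud 3538, 3447, 2138, 2814 and 8062 genes at weeks 3, 6, 9, 12 and 15, where the highest of the other splits gave 0, 1, 0, 0 and 0. It gave 1232 and 1428 at weeks 16 and 18 after ethylene (highest other 1 and 1), and 13824 and 13404 for control weeks 9 and 18 against week 0 (highest other 0 and 1). In flesh it gave 1051, 3706, 639, 294 and 4239 (highest other 1, 1, 2, 10 and 1), 2823, 72 and 9 at weeks 16, 17 and 18 after ethylene (highest other 1, 1 and 3), and 7802 and 7402 for the controls (highest other 2 and 1). The tissues at week 0 gave 12681 (highest other 0). In each of these the real split gave the most genes, which is the smallest share that 35 splits can give. The shares were not adjusted over the comparisons, so they do not exclude chance for each one singly. Most real counts lay far above the other splits, while flesh of week 18 after ethylene rests on 9 genes against 3. For bud week 17 after ethylene the real split gave 0 with edgeR (the fit with only the groups compared in the part above had 2345 at an unadjusted p under 0.05, and DESeq2 on all bud libraries called 4133), as did all 35 splits, so the splits decide nothing there.

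With 100 drawn splits, the real split gave 7713 genes for the mean effect in bud (highest of the other splits 2928), 2935 in flesh (198), 5072 for week 15 minus week 3 in bud (4003), 20914 and 14454 for any control week in bud and flesh (1508 and 609) and 1835 for the tissue difference (4), and no other split reached it. For the change to week 18, 3 splits in bud and 4 in flesh, the real one included, gave as many genes as the real 4790 and 818, and the highest others gave 5450 and 2741. For week 15 minus week 3 in flesh 3 splits reached the real 2359, and the highest other gave 3508. The shares lie under 0.05, the limit of the rule set, but were not adjusted over the comparisons. For week 15 minus week 3, the change to week 18 and the tissue difference, the drawn labels also mix the ethylene effect itself. Those splits therefore cannot tell whether the effect differed between weeks or tissues. Chance is not excluded where another split reached the real count. The highest split in flesh, several times the real count for the change to week 18, points to a structure of the samples. That structure can include the ethylene grouping itself, since labels drawn within each week can leave it in place in 1 week and mix it in the other; the splits above the real count were not examined further.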
